A study of Mus musculus with 6 samples.

How the data were processed

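Total RNA of 3 samples titled spermatogonial stem cells and 3 titled total testicular cells from transgenic mice was extracted with Trizol, labelled with biotin and hybridised to 1 array each, per the labels' protocols. The values are the processed probe set summaries that the authors deposited, on a log2 scale as the range of the values shows (lowest 1.20, highest 13.2, near-equal medians). The submitters' processing notes name MAS5 and RMA, with no version or role, so which of them made the values, with what background correction and normalization, is not given in the sources used here. Per the file headers, all 6 arrays shared 1 chip lot, 1 scanner and 1 scan day, and ran in 3 fluidics rounds (run starts less than 15 minutes apart counted as 1 round) on different fluidics modules. Rounds and modules were treated as possible batches. Detection calls and probe-level intensities were not used here. Signal above background takes the place of depth: background was the 95th percentile of 27 bacterial control probe sets. On the hybridization control probe sets the arrays averaged 8.51, 8.37 and 8.42 (total testicular cells) and 8.96, 8.45 and 8.38 (stem cells).

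Groups and replicate numbers came from the sample titles. The design, the tests, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The deposited log2 values were used as they stand, without a filter on dim probe sets, and 64 control probe sets were left out of the tests. Of the 22626 tested, 20380 were annotated to 1 gene, 691 to several and 1555 to none; no gene was named from a probe set with several. Gene identifiers of 20351 probe sets were found in the reference gene table (mouse assembly GRCm38.p6), which changed 0 symbols and placed genes on chromosomes. Each gene was represented by the probe set with the highest mean over the 6 arrays, and its adjusted p is the one over all probe sets. For several named genes whose probe sets disagree, the other values are given with the gene.

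Stem cell arrays were compared with total testicular cell arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 4 residual and 5.21 prior degrees of freedom, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05, and with a log2 difference of at least 1 as an added criterion. All differences are stem cells minus total testicular cells. Fold values are derived from log2 differences. Camera tested 25 gene lists (527 entries, 462 measured), 21 chromosomes and 162 families of at least 10 genes whose symbols share the letters before the first digit, each against all other genes, with a preset correlation of 0.01 and adjustment within each of these 3 sets of tests. It was repeated with a correlation estimated from the data, with which no list, chromosome or family passed. Fry, which tests whether a list moves on balance in 1 direction or, in its mixed form, in either, was a further alternative. The lists are markers of undifferentiated and differentiating spermatogonia, meiotic and haploid germ cells, the piRNA pathway, Sertoli, Leydig, myoid, matrix, endothelial, macrophage, lymphocyte and erythroid cells, antigen presentation, myeloid PU.1 targets, ETS factors, pluripotency, immediate early, heat shock and inflammatory genes, G1/S and G2/M phases, oxidative phosphorylation, glycolysis and epigenetic regulators.

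Named genes were the 12 largest increases and the 12 largest decreases among genes past the threshold with non-overlapping groups, Spi1, up to 4 members of each list past the threshold, and 18 marker genes whatever their result. Insl3, one of those markers, was not analysed here. Clones without a gene name were counted and skipped. Genes named outside the rule, chosen after their values were seen, are Aif1, Itgam, Msr1, Ccl4, Ciita, Hsd3b1, Cyp17a1, Star, Fos, Zfp36, Tpx2, Nusap1, Epcam, Vsig4, Lamp2, Atp6ap2, Ctsc, Ctsb, Ctsz, Ctsm, Cts7, Grn, Lgmn, Psap, Stab1, Gas6, Mertk and Trem2.

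The settings fixed in this way were quantile normalization, median centring, a filter on dim probe sets, the replicate number as a block, the fluidics round as a block, no intensity trend, robust empirical Bayes, array weights, leaving out each array in turn, a stricter threshold, an ordinary unmoderated test, other ways to represent a gene, other set tests, and the macrophage and PU.1 lists without shared genes. Centring on hybridization controls, the fluidics module as a block, and alternatives for the family scan were chosen after seeing the data. Alternatives for linear values did not apply. The procedure was tested on simulated data: with 200 of 22626 probe sets changed between groups with the spread of these arrays, limma recovered 58.2% of 67 changes of log2 1, 89.6% of 67 of log2 2 and 100% of 66 of log2 4, with 9 false calls among 174. A simulated shift of 1 list was called, with 0 of 23 lists sharing no gene with it. The simulated noise was independent between genes and alike in both groups, whereas members of the real lists are correlated (estimate 0.720 for the macrophage list). These simulations therefore do not show how often lists or probe sets are falsely called in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.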

Results

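Gene expression was measured in 6 mouse testis cell samples, each hybridised to 1 Affymetrix Mouse430A_2 array, a chip on which groups of short probes (probe sets) report transcript levels. The mice carried a human CD4 surface marker under a shortened promoter of Stra8, a germ cell gene, and magnetic beads against that marker isolated positive cells from pooled testes, with 50 males used for each stem cell preparation. In 3 arrays the title named spermatogonial stem cells, the germ cells that maintain sperm production, and in 3 it named total testicular cells. For the second group the title and the source description differ, since the source names cells negative for the marker. The 6 array records carry a single sample-type text. The comparison asked which transcripts were higher in the stem cell preparations, with Spi1, the gene of the transcription factor PU.1, as the gene of the series title. Of the 22690 probe sets, 64 controls were set aside and 22626 were tested, covering 12393 named genes. Median log2 values were 3.28, 3.28 and 3.25 on the total testicular cell arrays and 3.44, 3.34 and 3.36 on the stem cell arrays. Between 79.7% and 84.1% of probe sets per array lay above a background of 2.15, taken from bacterial control probe sets. The total testicular cell arrays correlated at 0.992 to 0.995 with one another and the stem cell arrays at 0.970 to 0.984, over probe sets, which are not independent replicates. Stem cell replicate 1 stood apart on the first principal component (72.9% of the variance), with a score of 78.7 against 18.8 and 15.3 for replicates 2 and 3.

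Macrophage transcripts rose most in the stem cell arrays. Csf1r, the receptor for the macrophage growth factor CSF1, was 27.1-fold higher, with a mean log2 value of 9.98 ± 1.01 (SD, n = 3) against 5.22 ± 0.52 (SD, n = 3) and a log2 difference of 4.76 ± 0.45 (SE, limma adjusted p = 0.00488). Lyz2, the macrophage lysozyme, rose 25.9-fold, from 5.36 to 10.06. Cd68, a lysosomal glycoprotein of macrophages, rose 20.2-fold, and Mrc1, the mannose receptor, 21.3-fold. Of the 31 measured genes of the macrophage and monocyte list, 19 rose, 0 fell and 12 did not pass. Adjusted over the list alone, 26 rose and 0 fell. The list's median log2 difference was 2.87, camera placed it above the other genes (adjusted p = 4.5e-26), and its adjusted p = 0.403 with an estimated correlation. The list's median difference from the mean of the total testicular cell arrays was 4.13, 2.10 and 2.27 on stem cell arrays 1, 2 and 3. Aif1 (log2 difference −0.11, adjusted p = 0.694) and Itgam (0.32, adjusted p = 0.472) did not pass. Aif1 was already at 9.72 on the total testicular cell arrays and Itgam at 2.14, just under background, so these 2 could hide a change. Msr1 (0.02, adjusted p = 0.957) did not rise either, at 5.29 on those arrays, well above background. Ccl4 (−0.30, adjusted p = 0.486) did not rise, but its 2.99 there lay within 2 log2 units of background, so a change could be missed.

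The largest increase of any named gene was that of F13a1, the A subunit of coagulation factor XIII, at 28.4-fold (log2 difference 4.83 ± 0.45 SE, adjusted p = 0.00488). Cbr2, a carbonyl reductase, rose by 4.75 on the log2 scale and Dab2, an endocytic adaptor, by 4.71. The other 9 of the 12 largest increases were Csf1r, Lyz2, Mrc1, Cd68, C1qc (4.58) and C1qa (4.38) of the complement component C1q, the immune receptor adaptor Tyrobp (4.55), the lysosomal protease Ctss (4.36) and Lyz1 (4.50). Lyz1 is nearly identical to Lyz2 and its probe sets ranged from 0.28 to 4.50, so its own change is uncertain. Those of Dab2 ranged from 1.15 to 4.71.

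**Figure D1:**
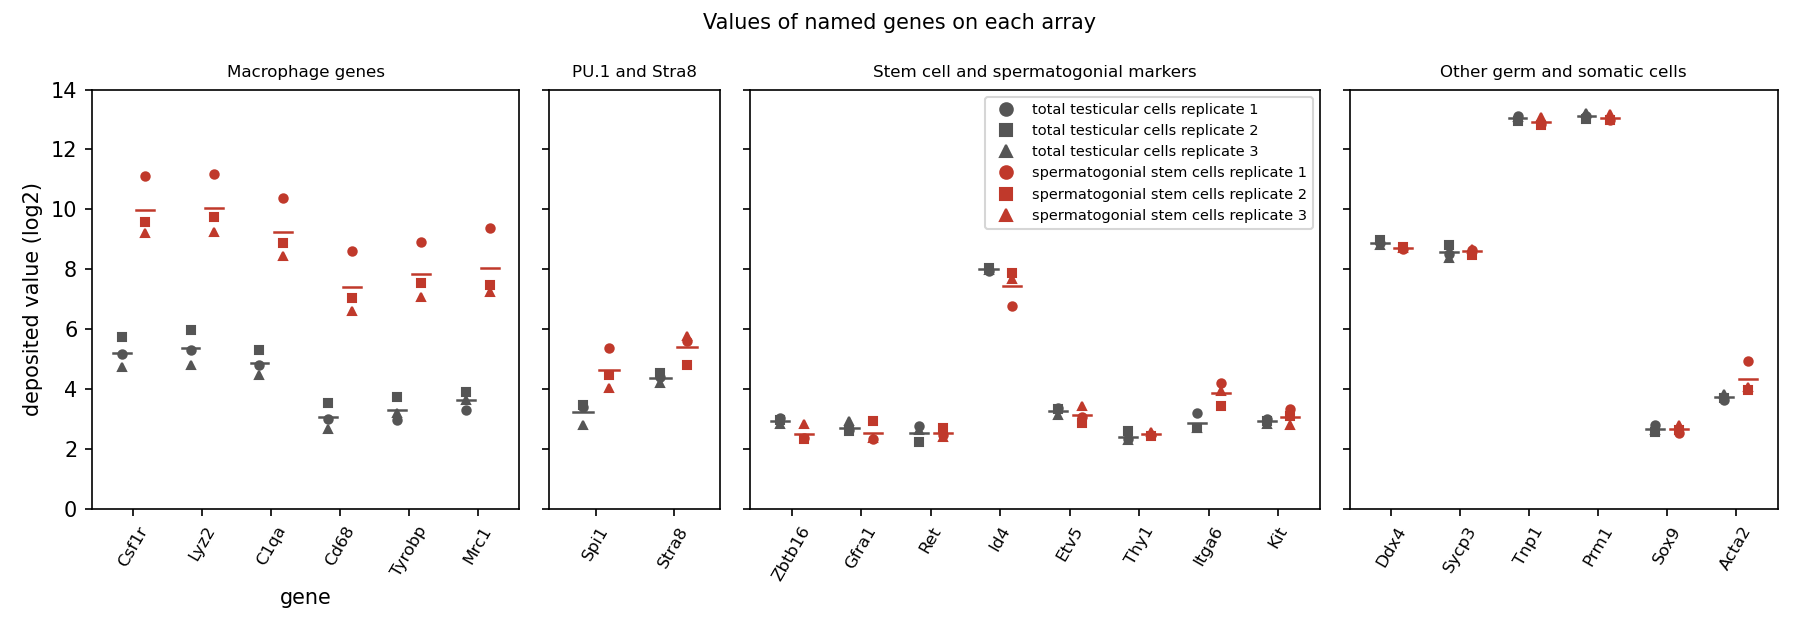
Deposited log2 values of selected genes on each array, grey for total testicular cells and red for stem cells, with points for arrays, marker shape for replicate number and bars for group means. Csf1r lay between 9.22 and 11.13 on the stem cell arrays and between 4.73 and 5.76 on the total testicular cell arrays, while Prm1 and Tnp1 lay near 13 on all 6.

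Genes of antigen presentation, steroid synthesis, extracellular matrix and the early response to stimulation also shifted upward as lists by camera, together with the macrophage list. With an estimated correlation none of these lists passed (adjusted p = 0.403 for each). In the antigen presentation list 4 of 15 measured members rose and 0 fell: H2-D1 (log2 difference 3.45, adjusted p = 0.00587, its 9 probe sets from 0.05 to 3.45) and B2m (3.37, adjusted p = 0.0145), the chains of a class I complex, and Cd74 (2.97, adjusted p = 0.0431) and H2-Aa (2.85, adjusted p = 0.0493) of class II. Adjusted over the list alone, 12 rose and 1 fell, Ciita, the class II activator (−0.33). Of 22 measured myeloid targets of PU.1, 4 rose and 0 fell: Csf1r, Cd68, the integrin chain Itgb2 (3.01, adjusted p = 0.00642) and the endotoxin receptor Cd14 (2.18, adjusted p = 0.0396). Adjusted over the list alone, 12 rose and 0 fell, and 8 of its genes also stand in the macrophage list. In the list of Leydig cells, the steroid-producing cells between the tubules, 0 of 13 measured members passed over all probe sets. All 13 differences were positive, 12 had an unadjusted p under 0.05, and 11 rose when adjusted over the list alone. Its members include Hsd3b1 (1.98, adjusted p = 0.0651), Cyp17a1 (1.92, adjusted p = 0.0742) and Star (1.85, adjusted p = 0.0972), which act in testosterone synthesis.

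In the matrix list, Igf1 (2.97, adjusted p = 0.0318), a growth factor, and Dcn (1.41, adjusted p = 0.0405), a proteoglycan, rose among 19 measured, and 7 rose when adjusted over the list alone. Among 24 immediate early genes, Btg2, an antiproliferative gene, rose (1.51, adjusted p = 0.0499, with 0.80 for its other probe set), and 11 rose when adjusted over the list alone. Fos (2.44, adjusted p = 0.0844) and Zfp36 (adjusted p = 0.0710) did not pass over all probe sets. Among 19 Sertoli cell genes, Clu, which encodes the secreted chaperone clusterin, rose (2.02, adjusted p = 0.0234), and 6 rose when adjusted over the list alone. Of 17 inflammatory cytokine genes, 0 passed by limma, 4 had an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. Median log2 differences were 1.29 for antigen presentation, 0.97 for PU.1 targets, 1.54 for Leydig cells, 0.90 for matrix, 1.03 for immediate early genes, 0.29 for Sertoli cells and 0.29 for inflammatory genes. By camera the adjusted p values were, in that order, 1.8e-08, 6.8e-09, 5.3e-08, 2.3e-07, 1.2e-08, 1.5e-04 and 0.00917. With an estimated correlation the adjusted p was 0.403 for the first 6 of these lists and 0.420 for the inflammatory list. Without stem cell replicate 1 the inflammatory list no longer passed (adjusted p = 0.135). Most of these shifts were uneven among the stem cell arrays: on arrays 1, 2 and 3 the Leydig cell median was 2.70, 1.27 and 0.51, and the immediate early median 2.08, 0.99 and 0.45. The Sertoli cell median was more even, at 0.26, 0.38 and 0.29.

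Spi1, the gene of PU.1, was 2.64-fold higher in the stem cell arrays and did not pass the threshold over all probe sets. Its log2 values were 5.37, 4.47 and 4.05 on the stem cell arrays and 3.41, 3.46 and 2.82 on the total testicular cell arrays, so that all 3 stem cell values lay above all 3 others. The log2 difference of its 1 probe set was 1.40 ± 0.33 (SE, n = 3 per group, limma adjusted p = 0.0684, unadjusted p = 0.00210). Spi1 differed by 2.25 within fluidics round 1 (a batch of arrays washed together) and by 1.01 within round 3. With the round as a block, the Spi1 level differed by 1.72 (adjusted p = 0.0261). Without stem cell replicate 3 the Spi1 level also passed (1.69, adjusted p = 0.0142). In the list of ETS transcription factors, the family of PU.1, only Elk3 of 23 measured members rose (1.14, adjusted p = 0.0435; its other probe sets reached down to −0.11, and its mean of 2.06 on the total testicular cell arrays lay below background, so the size is uncertain), and 2 rose when adjusted over the list alone.

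Most markers of undifferentiated spermatogonia did not differ detectably between the groups. Of 28 measured members, 2 rose and 0 fell: Dusp6, a phosphatase that limits ERK signalling (2.86, adjusted p = 0.0212), and Itgb1, the integrin beta 1 chain (1.58, adjusted p = 0.0470), whose probe sets ranged from −0.03 to 1.88. Adjusted over the list alone, 3 rose and 0 fell. Zbtb16, a repressor needed for stem cell maintenance (−0.43, adjusted p = 0.178, with 0.14 for its other probe set), and Id4, an inhibitor of differentiation (−0.55, adjusted p = 0.232), did not pass. Neither did Gfra1 (−0.17, adjusted p = 0.636) and Ret (−0.02), the receptor components for the niche factor GDNF. The same held for Etv5 (−0.15), Thy1 (0.09) and Itga6 (0.99, adjusted p = 0.0739). The other probe set gave 0.17 for Etv5 and −0.05 for Itga6. Signal limits this comparison: in the total testicular cell arrays 25 of the 28 lay within 2 log2 units of background or below, and Zbtb16, for example, had means of 2.95 and 2.52. The list's median was −0.02 and its mean 0.16, with camera pointing upward (adjusted p = 0.299). Stra8, the gene whose promoter drove the sorting marker, was 2.01-fold higher (log2 difference 1.01 ± 0.26 SE, adjusted p = 0.0832). It passed without stem cell replicate 2 (1.30, adjusted p = 0.0220). Itga6 also passed without that array (adjusted p = 0.0339). Kit, the receptor of differentiating spermatogonia, differed by 0.16 (adjusted p = 0.617), and by 0.70 on its other probe set. Of the 11 measured genes of that stage, 0 passed by limma, 1 had an unadjusted p under 0.05 and 1 rose when adjusted over the list alone (median 0.14, adjusted p = 0.145).

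Transcripts of later germ cells were abundant in both groups. Prm1, a protamine that packs sperm DNA, averaged 13.06 in the stem cell arrays and 13.11 in the others (log2 difference −0.05 ± 0.08 SE, adjusted p = 0.740). Tnp1, a transition protein of spermatids, averaged 12.91 and 13.04 (−0.13, adjusted p = 0.399). Prm1 was the highest value of the array on 4 of 6 arrays and Tnp1 lay close to the top, so a difference at these 2 genes could be hidden by saturated probes. Sycp3, of the meiotic chromosome axis, differed by 0.02, and Ddx4, a germ cell RNA helicase, by −0.17, and neither passed. As lists, 5 groups lay lower than other genes by small amounts in camera, and missed the threshold with an estimated correlation (adjusted p from 0.420 to 0.597). All 19 measured G2/M phase genes had negative differences (median −0.38, camera adjusted p = 5.9e-05). They include Tpx2 (−0.84, adjusted p = 0.0783) and Nusap1 (−0.69, adjusted p = 0.0956), both of the mitotic spindle. All 12 measured genes of the piRNA pathway were also negative (median −0.38, adjusted p = 0.00621). The medians were −0.22 for 24 meiotic genes (adjusted p = 0.0165), −0.25 for 19 epigenetic regulators (adjusted p = 0.0203) and −0.19 for 21 spermatid genes (adjusted p = 0.0216). No member of these 5 lists passed over all probe sets by limma, whereas 7, 5, 11, 3 and 2 were lower at an unadjusted p under 0.05, in the order given. Over all genes, 1625 of 12393 were lower at that p, a share that the 2 of 21 spermatid genes did not exceed. Adjusted over the list alone, 3 G2/M genes fell, and 0 members of the others passed. With an estimated correlation the adjusted p was 0.420 for the first 2 lists, 0.565 for meiotic genes and regulators, and 0.597 for spermatid genes. Without stem cell replicate 1 the list meiotic spermatocytes, the list haploid spermatids and the list epigenetic regulators no longer passed (adjusted p = 0.0515, 0.135 and 0.108). The spermatid list also missed the threshold without total testicular cell replicate 1 or 3 or stem cell replicate 2 (0.0594, 0.160 and 0.139), and the epigenetic list without total testicular cell replicate 3 (0.0639). With the fluidics module as a block, the list G2/M phase (adjusted p = 0.0570) and the list pan germ cell and piRNA pathway (0.176) missed it as well.

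**Figure D2:**
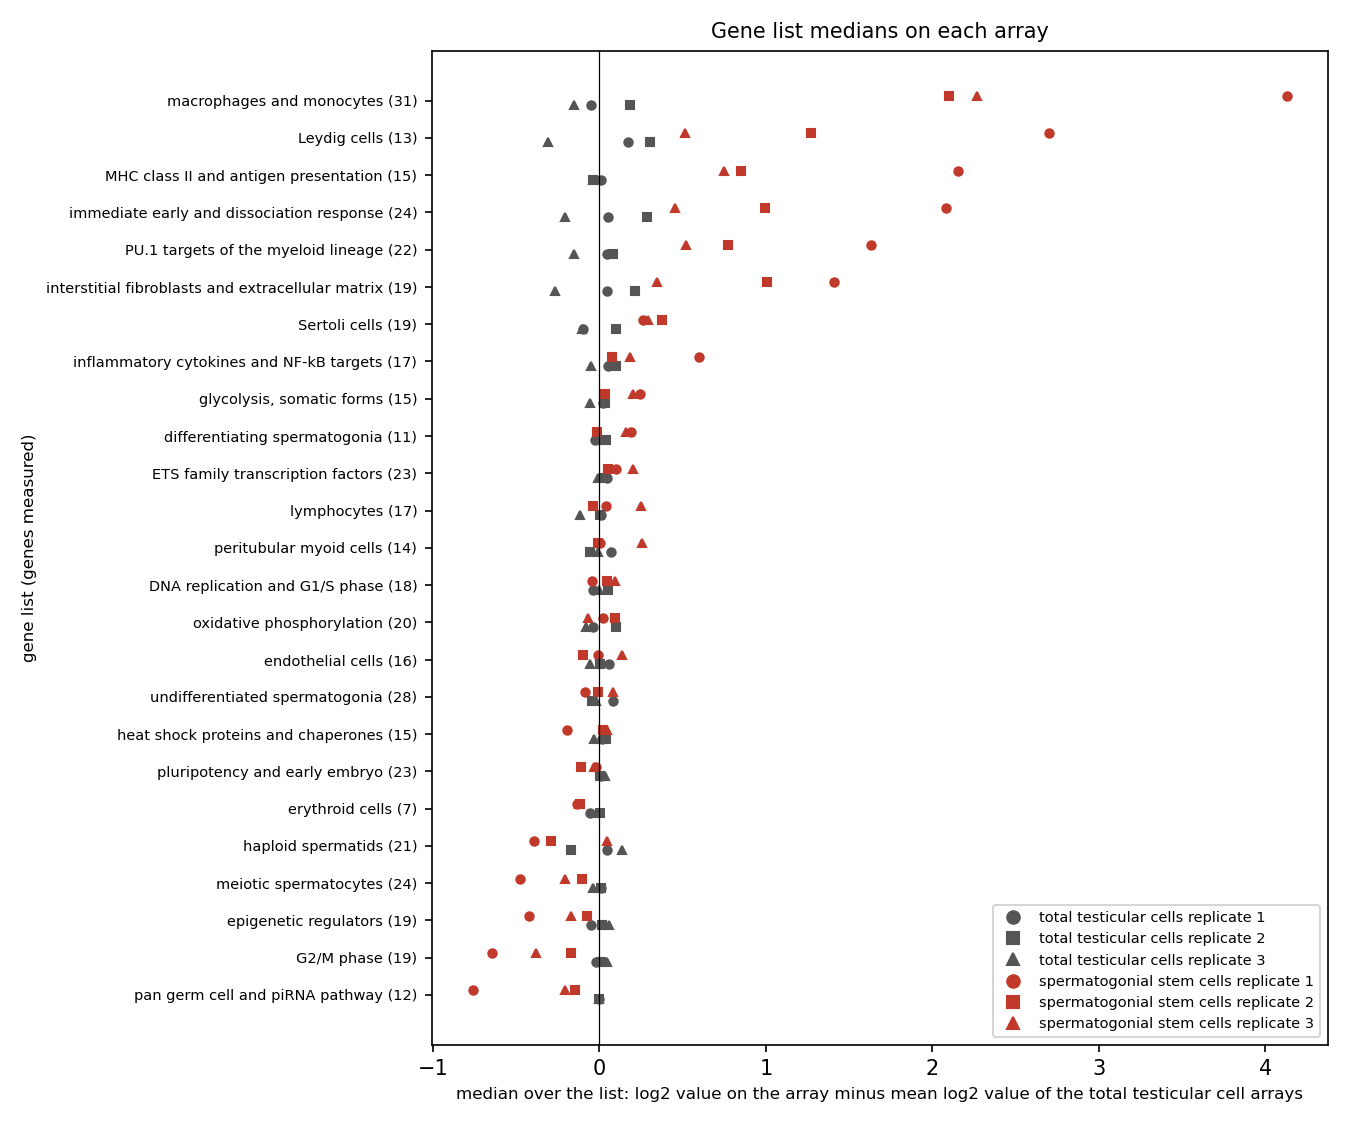
Median of each of 25 gene lists on each array, as the log2 difference from the mean of the total testicular cell arrays, grey for total testicular cells, red for stem cells, with marker shape for replicate number. The macrophage list lies at 4.13, 2.10 and 2.27 on the stem cell arrays, and the spermatid list at −0.39, −0.29 and 0.05.

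At the adjusted threshold 17 genes fell and 202 rose. At an unadjusted p under 0.05, 1625 genes were lower and 1458 higher, and the groups did not overlap for 2377 lower and 1706 higher genes (32.9% of genes, where chance gives 10%). Without stem cell replicate 2, the genes changed were 527 lower and 414 higher. The largest decrease was that of Pabpn1, a nuclear poly(A)-binding protein gene, which fell by 1.82 on the log2 scale (± 0.31 SE, adjusted p = 0.0327), while other probe sets of Pabpn1 reached only −0.12. Fbxw5, a substrate adaptor of a ubiquitin ligase, fell by 1.28 (adjusted p = 0.0405) and Necab3 by 1.32 (adjusted p = 0.0308). Among transcription factor genes, Sox17 fell by 1.12 (adjusted p = 0.0492) and Gfi1, a repressor, by 1.08. The remaining 7 of the 12 largest decreases were Rnf112, Speer4a, Slc12a5, Tanc1, Trpc2, Mdm1 and Ppp6r2, with log2 differences from −1.15 to −0.89. Further probe sets did not move alike for Rnf112 (up to −0.28), Sox17 (up to −0.24) and Slc12a5, a potassium chloride cotransporter gene (up to 0.02). Leaving out any 1 of the total testicular cell arrays left none of these 17 past the threshold (0 genes lower by limma, against 1625 lower and 1458 higher at an unadjusted p under 0.05 with all arrays). Without total testicular cell replicate 1, 2 or 3 the gene Pabpn1 still differed by −1.82, −1.85 and −1.78 (adjusted p = 0.182, 0.117 and 0.169).

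Markers of the remaining cell types and processes showed no list shift that passed. Signal limits this as well. On the total testicular cell arrays most endothelial, lymphocyte, myoid and erythroid genes lay within 2 log2 units of background or below, so changes could be missed. Sox17 was the 1 of 16 endothelial genes past the threshold, also when adjusted over the list alone (list median 0.01, adjusted p = 0.987). Ighm, the heavy chain of immunoglobulin M, rose among 17 lymphocyte genes (2.05, adjusted p = 0.0415), with its probe sets ranging from −0.36 to 2.41, and it was also the 1 gene past the threshold when adjusted over the list alone (list median 0.07, adjusted p = 0.170). The mouse gene Cd4 differed by 0.35 (adjusted p = 0.283), and by −0.18 on its other probe set. Among 14 peritubular myoid genes, 0 passed by limma, also when adjusted over the list alone, while 5 had an unadjusted p under 0.05 (median 0.07, adjusted p = 0.0702). Acta2, the smooth muscle actin, differed by 0.60 (adjusted p = 0.204), and by 0.07 on its other probe set. Sox9, a Sertoli cell transcription factor, differed by −0.01. In the lists of erythroid cells (7 measured, median −0.12, adjusted p = 0.639), pluripotency (23, −0.09, 0.513) and DNA replication (18, 0.06, 0.630), 0 members passed by limma, also when adjusted over the list alone, against 1, 3 and 4 at an unadjusted p under 0.05. Of all 12393 genes, 3083 lay under that p. Adjusted over the list alone, 4 heat shock genes, 4 genes of oxidative phosphorylation and 2 of glycolysis rose, with 0 over all probe sets. Their list medians were −0.09 of 15, 0.02 of 20 and 0.20 of 15 (adjusted p = 0.407, 0.190 and 0.126). For heat shock genes the mean was 0.20 and camera pointed upward. The ETS list had a median of 0.12 (adjusted p = 0.0738). Single arrays brought some of these past the threshold: the list oxidative phosphorylation passed without total testicular cell replicate 2 or stem cell replicate 3 (adjusted p = 0.0441 and 0.0299), the list peritubular myoid cells without total testicular cell replicate 1 or stem cell replicate 2 (0.0351 and 0.0410), and the list lymphocytes without stem cell replicate 2 (0.0466). The medians of the myoid, endothelial, lymphocyte, ETS, DNA replication, oxidative phosphorylation and differentiating spermatogonia lists changed sign under hybridization control centring, and some of them under median centring, which lower all genes alike. Under quantile normalization the endothelial median alone did so (−0.03).

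In all, 350 probe sets passed the limma test at a Benjamini-Hochberg adjusted p under 0.05, 316 higher and 34 lower (90.3% higher), and 314 of them differed at least 2-fold, 292 higher and 22 lower. Of the 350, 13 carried no gene name and 20 were annotated to several genes. Counting each gene by its representative probe set, 219 genes passed (202 higher, 17 lower), of which 204 differed at least 2-fold. Of the 202 higher genes, 32 were in a fixed list. At an unadjusted p under 0.05 there were 5328 probe sets, 2580 higher and 2748 lower. The groups did not overlap for 30.9% of probe sets (3048 higher, 3953 lower), where chance gives 10%. The number of probe sets changed rested on single arrays, with 36, 67 and 51 without total testicular cell replicate 1, 2 or 3 and 567, 1622 and 1523 without stem cell replicate 1, 2 or 3. The corresponding genes changed numbered 28, 47 and 36, and 346, 941 and 889, and without stem cell replicate 2 the lower genes (527) outnumbered the higher (414). Centred on hybridization controls, 1331 probe sets changed (844 higher, 487 lower, 63.4% higher), centred on medians 454 did (363 higher, 91 lower), with the fluidics round as a block 1284 did, and with the fluidics module as a block, which leaves 1 residual degree of freedom, 0 did (lowest adjusted p = 0.0721, 3537 at an unadjusted p under 0.05).

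The shifts of the lists were recomputed within fluidics rounds. Round 1 held 1 stem cell array and 2 of total testicular cells, round 3 held 1 of each, and round 2 a single stem cell array. The macrophage list differed by 4.21 in round 1 and 2.16 in round 3, with 3.18 when the round was a block for the list macrophages and monocytes. Medians in rounds 1 and 3 were 2.80 and 0.94 for Leydig cells, 2.31 and 0.57 for antigen presentation, 1.76 and 0.64 for PU.1 targets, 2.19 and 0.77 for immediate early genes, and 1.48 and 0.80 for matrix. The median was 0.31 and 0.17 for Sertoli cells and 0.67 and 0.03 for inflammatory genes. Among the lower lists it was −0.67 and −0.16 for G2/M genes, −0.77 and −0.12 for the piRNA pathway, −0.48 and −0.12 for meiotic genes, −0.45 and −0.12 for epigenetic regulators, and −0.55 and −0.06 for spermatid genes. Module 2, the 1 module with both groups, held 1 array of each, which differed by 2.20 for the macrophage list and by 1.65 for Spi1. The labels do not say in so many words that replicates were separate preparations, so p-values measure only the spread between these arrays, and the number of arrays limits the precision.

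X-linked genes were higher as a group in the stem cell arrays. The 402 measured genes had a median log2 difference of 0.15, and 70.4% were positive, against a median of −0.06 and 42.0% for 11957 autosomal genes. Of the X-linked genes 13 rose and 0 fell, among them Vsig4, a macrophage complement receptor (3.73, adjusted p = 0.0262), Lamp2, a lysosomal membrane protein (2.36, adjusted p = 0.0368), and Atp6ap2, an accessory subunit of the vacuolar proton pump (2.13, adjusted p = 0.0187). Camera placed the X above other genes (adjusted p = 5.6e-08, and adjusted p = 0.483 with an estimated correlation), and the other 20 chromosomes had an adjusted p of 0.990. The X median was 0.17, 0.08 and 0.19 on stem cell arrays 1, 2 and 3. Within fluidics rounds 1 and 3 it was 0.18 and 0.07, where autosomes had −0.11 and −0.06, and within the shared module it was 0.12. With the round as a block, the median of X-linked genes was 0.12. The 8 measured Y-linked genes had a median of −0.18. Centring on hybridization controls, which moved all probe sets down, put the median of X-linked genes at −0.01, still above the other genes by camera (adjusted p = 2.2e-05).

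**Figure D3:**
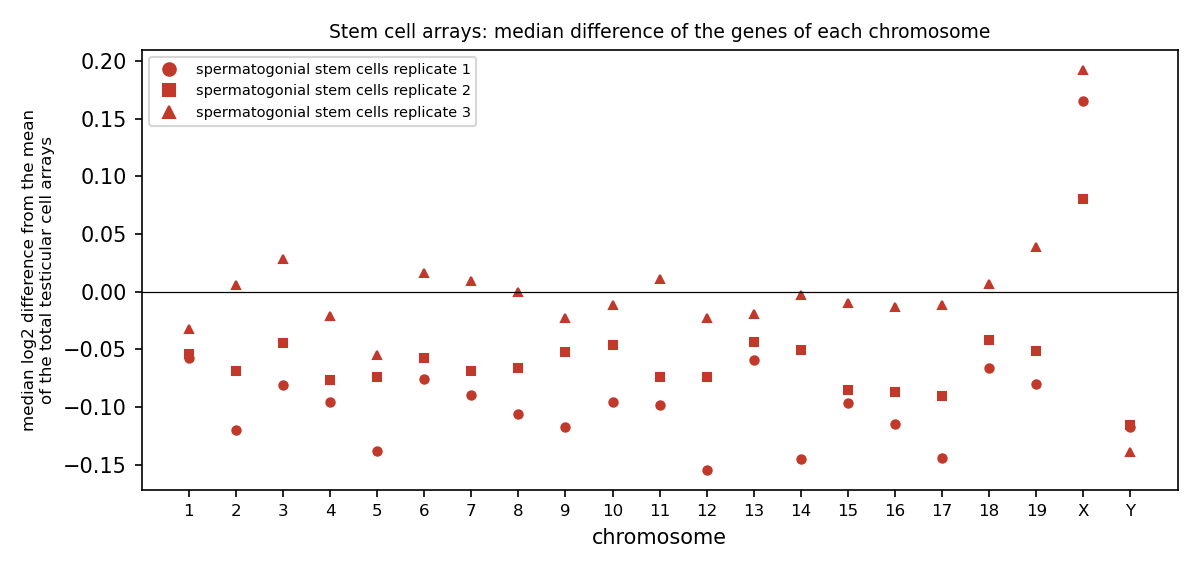
Median log2 difference of the genes of each chromosome on each stem cell array, relative to the mean of the total testicular cell arrays, with points for arrays. The X lies at 0.17, 0.08 and 0.19, and the autosomes together at −0.10, −0.07 and −0.01.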

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

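The tests of the macrophage and Spi1 patterns, and the test of macrophage RNA for the X-linked pattern, were chosen only after the result was seen.

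Among the array's control probe sets, which lie outside the main measurement, 7 of those for mouse transcripts had all stem cell arrays above all total testicular cell arrays at a level above background. The log2 differences were 0.50, 0.36 and 0.57 for the 3′, 5′ and middle parts of beta-actin, 0.81, 0.96 and 0.73 for the 3′, 5′ and middle parts of Gapdh, and 0.23 for the 3′ part of pyruvate carboxylase. All 7 stayed positive under quantile normalization, median centring and centring on hybridization controls. Other parts of pyruvate carboxylase differed by −0.09, 0.03 and −0.09, of which the second turned negative under each of these 3 scalings. The 3′ minus 5′ value of Gapdh was −0.10, −0.18 and −0.04 on the total testicular cell arrays and −0.45, −0.43 and 0.09 on the stem cell arrays. That of beta-actin went the other way on average, with 0.32, 0.45 and 0.24 against 0.58, 0.41 and 0.45.

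Macrophage genes were higher in the stem cell arrays, with a list median of 2.87 on the log2 scale. The authors' scaling is argued against by ranks within arrays, where the list's median lay 40.0 percentile points higher on average, at 91.1, 76.3 and 74.8 on the stem cell arrays against 41.3, 42.6 and 38.4. The fluidics round as the whole cause is argued against by the shift within rounds, at least 2.16 where both groups were present. RNA from macrophages in the positive fraction stays open. Over the 26 members with every stem cell array above every total testicular cell array, 5 being left out, the log2 ratios of linear excess between stem cell arrays had interquartile ranges of at most 0.509. This does not name a source, since 98.7% of 2000 sets of other genes with a like difference also stayed under the limit of 1, and 17.2% were as narrow as the list. Lyz2 and Csf1r had means of 10.06 and 9.98 on the stem cell arrays. Selection for the huCD4 marker is meant to remove cells lacking it, and how macrophages might pass was not tested. How far other cells were removed was not tested either. Sycp3, of later germ cells, stood at 8.60 against 8.57, and the Leydig cell list had a median difference of 1.54. Expression by the stem cells themselves stays open too, since the markers at a usable level numbered 3 (median −0.55). Of the 31 genes, 29 were above background in the total testicular cell arrays, where 79.9% to 81.3% of all probe sets were too.

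Spi1 was higher on each stem cell array, by 1.40 on average, without passing the threshold in the limma test. RNA from macrophages stays open as an explanation. The log2 ratios of linear excess of Spi1, −1.34 and −2.18 for replicates 2 and 3 over replicate 1, lay within 0.658 robust SDs of the macrophage list's medians of −1.60 and −2.05, but 40% of 100 other genes with a like difference lay within 2. Expression in cells with endogenous Stra8 was not settled. In robust SDs of the macrophage list, Spi1 lay 1.77 from Stra8 in one ratio and −11.1 in the other, where Stra8 had −2.04 and 0.26. The second distance is large on the scale of the macrophage list, whose robust SD in that ratio was 0.220. Leydig cell genes had an interquartile range of 1.74 in the same ratio, so 1 cell type's genes can spread widely there. The second ratio also rests on stem cell replicate 3 and on 1 probe set of each gene, so it does not exclude this explanation. Expression of Spi1 by the stem cells was not tested apart from this.

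X-linked genes were higher as a group, by a mean of 0.30 on the log2 scale. Intensity-dependent scaling is argued against, since that mean lay at percentile 100 of 10000 random autosomal sets matched on level, whose central range was −0.01 to 0.09. Such sets take genes as independent, whereas X-linked genes were correlated (estimate 0.032), and 6 other splits of the arrays also called the X by camera. The percentile therefore overstates the certainty. A larger share of premeiotic germ cells, which have not silenced the X, stays open: 13 X-linked genes known from spermatogonia had a median of 0.16 against 0.15 for the others, at percentile 52.4 of random X-linked sets, and most lay near background. RNA from macrophages also stays open, as the median excess ratios of 120 X-linked genes (−1.34 and −1.35) lay 0.648 robust SDs from the macrophage list in one ratio and 3.18 in the other. RNA of other somatic cells was not tested for this pattern, though the Leydig cell and matrix lists had median differences of 1.54 and 0.90.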

How the results depend on the processing

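Fits with the fluidics module as a block or with arrays centred on hybridization controls, and all alternatives of the family scan, were tests chosen after the result was seen. Probe sets changed, probe sets changed at least 2-fold and genes changed numbered 350, 314 and 219 as reported. They numbered 125, 114 and 82 without the intensity trend, 1001, 683 and 603 with array weights, 1284, 1097 and 767 with the fluidics round as a block, and 1331, 1027 and 737 with centring on hybridization controls (63.4%, 69.0% and 70.0% higher, against 90.3%, 93.0% and 92.2%). With the module as a block, which leaves 1 residual degree of freedom, they numbered 0, 0 and 0 in limma, with 3537 probe sets at an unadjusted p under 0.05, and the symbol family scan called 3 families against 14. At an adjusted p under 0.01, 53 probe sets passed; an ordinary unmoderated test passed 0, with 3593 at an unadjusted p under 0.05. Averaging all probe sets of a gene gave 100 genes. Quantile normalization, median centring, the filter on dim probe sets and robust empirical Bayes gave 261, 454, 385 and 359 probe sets and kept 161, 213, 195 and 218 of the 219 genes; hybridization control centring kept 204. Median centring and hybridization control centring moved the median of all differences from −0.03 to −0.15 and −0.20, so changes under them are relative to that shift. Apart from what the construction of the module fit shows, the cause was not tested.

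Leaving out 1 array at a time gave 36 to 1622 probe sets changed, 36 to 1127 probe sets changed at least 2-fold and 28 to 941 genes changed, the lowest without total testicular cell replicate 1 and the highest without stem cell replicate 2 (replicate 3 for 2-fold). Without total testicular cell replicates 1, 2 and 3, 28, 47 and 36 of the 219 genes still passed, and without stem cell replicates 1, 2 and 3, 209, 212 and 219. The cause was not tested.

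The Spi1 level ranged from 1.03 to 1.72 over 17 alternatives (adjusted p from 0.00117 to 0.274) and passed in 5: the replicate block (1.40, adjusted p = 0.00891), array weights (1.24, 0.0379), the round block (1.72, 0.0261), hybridization control centring (1.23, 0.00117) and without stem cell replicate 3 (1.69, 0.0142); leaving out 1 array gave 1.03 to 1.69. The list macrophages and monocytes ranged from 2.20 to 3.75 over 20 alternatives and missed the threshold in 2, camera with an estimated correlation (2.87, adjusted p = 0.403) and fry (2.87, adjusted p = 0.0575). X-linked genes ranged from −0.01 to 0.25 over 17 alternatives and missed it with an estimated correlation (0.15, adjusted p = 0.483). With that estimate 0 gene list tests, 0 chromosome tests and 0 families passed in camera, against 1, 1 and 1 at an unadjusted p under 0.05, and fry passed 0 lists, with 9 unadjusted. Its test for change in either direction passed 8 lists: macrophages, undifferentiated spermatogonia, Sertoli cells and ETS factors (adjusted p = 0.0303), myoid cells (0.0292), and antigen presentation, PU.1 targets and glycolysis (0.0362). That test does not compare a list with other genes, and 3083 of all 12393 genes had an unadjusted p under 0.05. Of 28 undifferentiated spermatogonia genes 4 were higher and 2 lower at that p, and of 23 ETS genes 5 and 1. Passing it therefore does not set these 2 lists apart from other genes. As a shift in 1 direction, undifferentiated spermatogonia passed in 0 of 20 alternatives (−0.19 to 0.32). The median of the meiotic list ranged from −0.39 to −0.04 over 20 alternatives and passed in 13. That of the spermatid list ranged from −0.44 to −0.10 and passed in 11. Of 499 other fits of the 25 lists, 443 stayed on the same side of the threshold, 48 lost the call and 8 gained one. In 0 did the direction reverse where either fit passed, while sign changes between fits that both missed it were not counted. Of 1376 fits for 77 single genes, the same counts were 1126, 217, 33 and 0.

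The labels do not say whether same-numbered arrays share animals, and the arrays were treated as unpaired. Deviations of same-numbered arrays from their group means correlated at −0.01, 0.01 and 0.30, and 2 of 6 arrays correlated best with their own number, which leaves pairing open. With the replicate block, probe sets changed numbered 1261, probe sets changed at least 2-fold 934 and genes changed 737, including all 219.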

Other observations

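The tests of the lysosomal and phagocytic gene groups were chosen after the result was seen; the family scan, the chromosome tests and the splits of the arrays were planned.

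Some genes of lysosomal proteases rose in the stem cell arrays. Of 22 measured cathepsins, 8 rose, 0 fell and 14 did not pass, and 1 of the 8, Ctss, belongs to the macrophage list. The others include Ctsc (log2 difference 4.26, adjusted p = 0.00488), Ctsb (3.73, adjusted p = 0.00898) and Ctsz (3.52, adjusted p = 0.0107). Several of the 14 lay at or below background in both groups. Examples are Ctsm (means of 1.98 on total testicular cell and 1.98 on stem cell arrays) and Cts7 (1.72 and 1.75). The group's median, which counts such genes, was 0.27, with 0.29 and 0.24 within fluidics rounds 1 and 3. Of 34 other lysosomal proteins, 7 rose and 0 fell, among them Grn, the progranulin gene (mean log2 8.95 against 4.96, adjusted p = 0.00660), the protease Lgmn (3.18, adjusted p = 0.00488) and Psap, the precursor of saposins (2.42, adjusted p = 0.0194). Their median was 0.47, with 0.95 and 0.22 within those rounds.

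Of 20 measured genes for the uptake of dying cells, 8 rose, 0 fell and 12 did not pass, with a median of 1.35 (2.12 and 0.92 within rounds 1 and 3). They include the scavenger receptor Stab1 (3.39, adjusted p = 0.00642), the receptor Trem2 (2.24, adjusted p = 0.0472, with 0.18 for its other probe set), the kinase Mertk (1.56, adjusted p = 0.0396) and its ligand Gas6 (2.55, adjusted p = 0.0121). On stem cell arrays 1, 2 and 3 the group's median was 2.03, 0.87 and 0.92. With an estimated correlation camera gave unadjusted p values of 0.0309 for cathepsins, 0.0910 for the other lysosomal proteins and 0.0846 for uptake genes.

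In the scan of 162 families, 14 passed by camera, 8 higher and 6 lower, and 0 with an estimated correlation (adjusted p = 0.847). The 26 measured small ribosomal subunit genes (Rps) had a median of 0.22, and 0.26 and 0.13 within rounds 1 and 3. The 12 intraflagellar transport genes (Ift), which build cilia and sperm tails, were all negative, with a median of −0.44, and −0.79 and −0.18 within those rounds. Both medians kept their sign under quantile normalization, median centring and hybridization control centring, while the last of these called 10 families, all higher. Large ribosomal subunit genes (Rpl) had a median of 0.16, and −0.01 under hybridization control centring, which lowered all genes alike (median of all differences from −0.03 to −0.20) and so left Rpl as it was relative to other genes.

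Epcam, a surface marker of undifferentiated spermatogonia and one of the few above background by over 2 log2 units, differed by −0.63 (adjusted p = 0.103). Among the stem cell arrays, the median log2 ratio of linear excess of replicate 2 over replicate 1 was −1.51 for 12 Leydig genes and −1.60 for 26 macrophage genes, and that of replicate 3 over replicate 1 was −2.89 and −2.05. The interquartile ranges were 0.747 and 0.509 for the former ratio and 1.74 and 0.287 for the latter, and no difference between the lists was tested.

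The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 350 probe sets, 314 at least 2-fold and 219 genes, and the other splits at most 0, 0 and 0 by limma, with at most 1837 probe sets at an unadjusted p under 0.05, so that in each case 1 split of 10 gave as many. For the lists the real split gave 13 and the highest other 14, with 2 splits giving as many. For chromosomes the real split gave 1 and the highest other 1, with 7 giving as many, and for families 14 and 22, with 3 giving as many. The 14 lists came from total testicular cell replicates 1 and 3 with stem cell replicate 2 against the rest. The gap between the X and autosome medians was 0.212 in the real split and at most 0.153 in size in the others, of which 6 called the X by camera.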
